A study of Homo sapiens with 4 samples.

How the data were processed

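RNA was measured on 4 expression arrays of AGS, a human gastric adenocarcinoma cell line. Per the labels, 2 arrays came from cells with wild-type PRMT6 (control) and 2 from PRMT6-knockout cells, and each array was placed in its group by the sample labels. Per the labels' protocols, a single guide RNA against PRMT6 was delivered in a lentiviral Cas9 vector, infected cells were selected with puromycin, and knockout clones were isolated by limiting dilution. The labels name neither the clone behind each knockout array nor the vector or clonal state of the control cells. The position of the guide in PRMT6 and the edits it made were not analysed here. Total RNA passed a threshold of RNA integrity, was amplified by a labelling method primed at the 3′ end of transcripts and carried biotin, per the labels' protocols.

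The authors deposited 1 table of log2 intensities with 54613 probe sets on each of the 4 arrays. RMA, which corrects background, quantile-normalizes probes and summarizes them per probe set, and the affy package are named in the submitters' processing notes, with no version. The log2 scale was read from the values, which ran from 1.64 to 14.16 with array medians of 5.01, 5.02, 5.02 and 5.02. Each array carries 1 sample, so the direction of a difference is set by the group labels. Detection calls and the manufacturer's control probe sets were not used here, so neither a background limit per probe set nor RNA quality along transcripts was assessed. Quantile normalization sets all arrays to nearly the same distribution, which removes any change in total RNA per cell and makes each difference relative to the other transcripts. RMA also compresses differences of dim probe sets. For arrays, the number of arrays limits the precision.

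Probe sets were named from the platform's gene annotation, and symbols were updated through Entrez gene numbers to the RefSeq gene table of assembly GRCh38.p14. Of the probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 were not listed with a gene; 41037 of those with 1 symbol matched the RefSeq table and 54 kept the symbol given. Genes were named only from probe sets with 1 symbol. Each of 19775 genes was represented by the probe set with the highest mean over the 4 arrays. Several probe sets were present for 10523 genes, and in 43 of these probe sets passed the test in opposite directions.

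Knockout and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, no covariates, all 4 arrays). P-values were adjusted by the method of Benjamini and Hochberg over all 19775 genes, and a gene was called at an adjusted p below 0.05. The design leaves 2 residual degrees of freedom per gene, to which the prior added 3.27. Fold changes are knockout minus control on the log2 scale, with the moderated standard error (SE) and 95% confidence intervals where given. Gene lists with at least 3 measured genes were tested with camera from limma, which asks whether a list's genes rank higher or lower than the other genes, at a preset correlation between genes of 0.01. Adjustment was over the 29 lists. Run as alternatives were camera with a correlation estimated per list, and fry. Fry tests whether a list's genes move on balance in 1 direction without comparing them with other genes. With an estimated correlation camera uses only the 2 residual degrees of freedom, so its p-values rise whether or not genes are correlated. The tests were tested on simulated data made from the 19775 real genes: 6.06% of genes changed by 0.5 on the log2 scale were recovered, 59.1% of those changed by 1 and 86.6% of those changed by 2. Of 104 genes called in the simulation, 2 had not been changed, 0 were called in the wrong direction, and 0 unchanged lists were called. The 1 changed list, G2/M and mitosis, was called. Simulated genes varied independently, so list calls among correlated genes were not tested. Outside that list 66 or 67 of the 19775 genes were changed at each size, far fewer than the 24.0% of genes called here. The adjusted p depends on that share, so the recovered shares do not give the sensitivity of this comparison.

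The groups, the tests, the 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were PRMT6, the 3 genes recalled from the published study of these cells, the 12 called genes with the largest rise and the 12 with the largest fall whose knockout arrays did not overlap the control arrays, and in each described list up to 4 called members with the largest change, or the 2 members with the largest change where none was called. Genes used to infer sex were left out of naming; 1 such gene was called. A gene outside this rule is named only where a count of 5 or fewer is spelled out or in the closing section, and was then chosen after its values were seen.

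The alternatives were the mean of a gene's probe sets, the brightest gene-specific probe set, only the brighter genes, an intensity trend or a robust prior in the moderation, median centring, a further quantile normalization, cyclic loess, the replicate number as a block, and leaving out each array in turn. Added after the data were seen were a scaling that equalizes the mean of the reference genes, a test of every probe set on its own, and list medians without members shared between lists. Pairing by replicate number was checked only by correlating deviations of arrays that share a number, which cannot exclude shared handling. Gene-specific probe sets were those whose names lack the suffix _s_at or _x_at, and they can be much dimmer than a gene's brightest. A gene kept its value if its brightest probe set was already gene-specific or if it had none. Only its adjusted p could then change. The closing section gives the effect of the alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

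The labels do not say whether the arrays of a group came from separate cultures or clones. P-values of single genes therefore measure only the spread between these arrays, which may be technical. Camera at the preset correlation takes genes as the units, so the size of its p-values does not measure spread between arrays or cultures. A difference between the groups covers everything that set the knockout cells apart from the control cells.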

Results

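Gene expression was profiled in AGS cells, a line derived from a human gastric adenocarcinoma, with wild-type PRMT6 (control, n = 2 arrays) or after knockout of PRMT6 with a lentiviral Cas9 vector (knockout, n = 2 arrays). PRMT6 is an arginine methyltransferase that places an asymmetric dimethyl mark on arginine 2 of histone H3. The series title places the comparison in a study of this mark in gastric cancer progression, and the comparison asks which transcripts differ when PRMT6 is disrupted. The log2 intensities of 54613 probe sets had a median of 5.01 to 5.02 on each array. Pearson's r across probe sets was 0.995 between the control arrays, 0.996 between the knockout arrays and 0.981 to 0.984 between arrays of different groups. Across genes, the difference between group means had an SD of 0.45 on the log2 scale, against 0.20 for the difference between the control arrays and 0.17 for that between the knockout arrays.

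PRMT6 itself was read by 1 probe set. Its log2 intensity was 8.07 ± 0.05 in control cells and 7.71 ± 0.11 in knockout cells (SD, n = 2), with control arrays at 8.03 and 8.11 and knockout arrays at 7.79 and 7.63. The transcript fell by 0.36 on the log2 scale (SE 0.09, 95% confidence interval -0.59 to -0.13), 1.28-fold, with an adjusted p of 0.043 from limma. It therefore remained readily measured in the knockout cells. A guide directed at the coding sequence need not lower the transcript, and a probe set outside the edited part does not test the edit. The call was lost with any single array left out: the change was -0.40 without control 1 (adjusted p = 0.10), -0.32 without control 2 (0.16), -0.44 without knockout 1 (0.11) and -0.28 without knockout 2 (0.23).

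In the knockout cells, genes of the unfolded protein and ATF4 stress response were lower, with 29 of 31 measured members past the test. Genes of mitosis (28 of 28), DNA replication (26 of 30) and cholesterol biosynthesis (15 of 17) were higher. The largest single rises were those of ODAM, ALDH1A1 and FGB, and the largest falls those of HSPA6, PASD1 and INHBE. By group means each of these 3 rises was over 60-fold, from control levels not known to exceed background. Of 19775 genes, 2459 rose and 2281 fell at an adjusted p below 0.05 in limma, together 24.0% of genes; 257 rose and 427 fell by 2-fold or more. At an unadjusted p below 0.05 there were 6890 genes, where 989 would be expected by chance. Knockout and control arrays did not overlap for 58.2% of genes, where chance gives 33.3%.

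These counts rested on all 4 arrays. Without control 1, 1371 genes rose and 1258 fell, and without control 2 there were 1025 and 1201. With a single knockout array, which is then assumed to vary like the controls, 196 genes rose and 374 fell without knockout 1, and 154 and 354 without knockout 2, where 150 rose by 2-fold or more. The direction split also rested on the scaling. Rises made up 51.9% of calls on the deposited scale and 10.3% when arrays were set to equal means of the reference genes, a scaling that moved the median of all genes from -0.01 to -0.31 on the log2 scale; by 2-fold or more, 138 genes rose and 923 fell under it. No named gene past the test changed sign under that scaling.

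ODAM, a secreted protein first known from tooth enamel, rose by 6.35 on the log2 scale (SE 0.12), from 4.36 ± 0.04 to 10.71 ± 0.23 (SD, n = 2), or 81.7-fold. ALDH1A1, which oxidizes retinaldehyde to retinoic acid, rose by 6.32 (SE 0.08), from a control level of 2.68 ± 0.04, or 80.1-fold. FGB, the beta chain of fibrinogen, rose by 6.01 (SE 0.33), from 4.83 ± 0.74 to 10.84 ± 0.03. AGR2, a disulfide isomerase of secretory epithelia, rose 13.6-fold (log2 3.76, SE 0.09), and ANXA1, a phospholipid-binding annexin, rose 13.1-fold (log2 3.71, SE 0.08). OLR1, a receptor for oxidized lipoprotein, rose 11.9-fold, SPATA17 11.5-fold and NAV3 9.37-fold. TMEM52B rose 8.98-fold and the long non-coding RNA LINC00973 8.80-fold. Adjusted p-values of these 10 genes in limma ran from 6.6e-05 for ALDH1A1 to 0.00070 for FGB. For ODAM, ALDH1A1, FGB, NAV3, TMEM52B and LINC00973 the control level (4.36, 2.68, 4.83, 4.58, 2.89 and 2.81), the lowest of these 10, lay below the median gene's level of 5.97. The control levels of OLR1 (4.97) and SPATA17 (5.10) lay below it too. Without detection calls it is not known whether these control levels exceeded background, so these folds are approximate.

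HSPA6, an inducible member of the HSP70 chaperones, fell by 6.42 on the log2 scale (SE 0.22), from 10.63 ± 0.29 to 4.21 ± 0.37 (SD, n = 2), or 85.4-fold. PASD1, a cancer-testis antigen, fell by 5.27 (SE 0.28), from 9.04 ± 0.08 to 3.76 ± 0.60. INHBE, the inhibin beta E subunit, fell by 4.86 (SE 0.28), and BHLHA15, a transcription factor of secretory cells, fell by 4.34 (SE 0.10). HKDC1, a hexokinase family member, was 19.1-fold lower, the lysosomal membrane protein LAMP3 17.3-fold and the endoplasmic reticulum oxidase ERO1B 16.9-fold. TEX19, a germ-cell gene, was 16.8-fold lower and the calcium-binding protein S100P 15.5-fold. Apolipoprotein APOA2 was 12.4-fold lower, the collagenase MMP1 10.5-fold and the gastric trefoil peptide TFF1 10.4-fold. The adjusted p-values of these 12 genes in limma lay between 0.00012 (BHLHA15, LAMP3 and APOA2) and 0.00084 (S100P). The knockout levels of HSPA6 (4.21), PASD1 (3.76), ERO1B (4.33) and TEX19 (4.36), the lowest of these 12, lay far below the median gene's 5.97. Those of BHLHA15 (4.94), INHBE (5.31) and LAMP3 (5.45) lay below it too. Without detection calls it is not known whether these knockout levels exceeded background, so these folds are approximate. The 24 genes with the largest rises and falls kept their calls under every alternative that tested them.

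**Figure D1:**
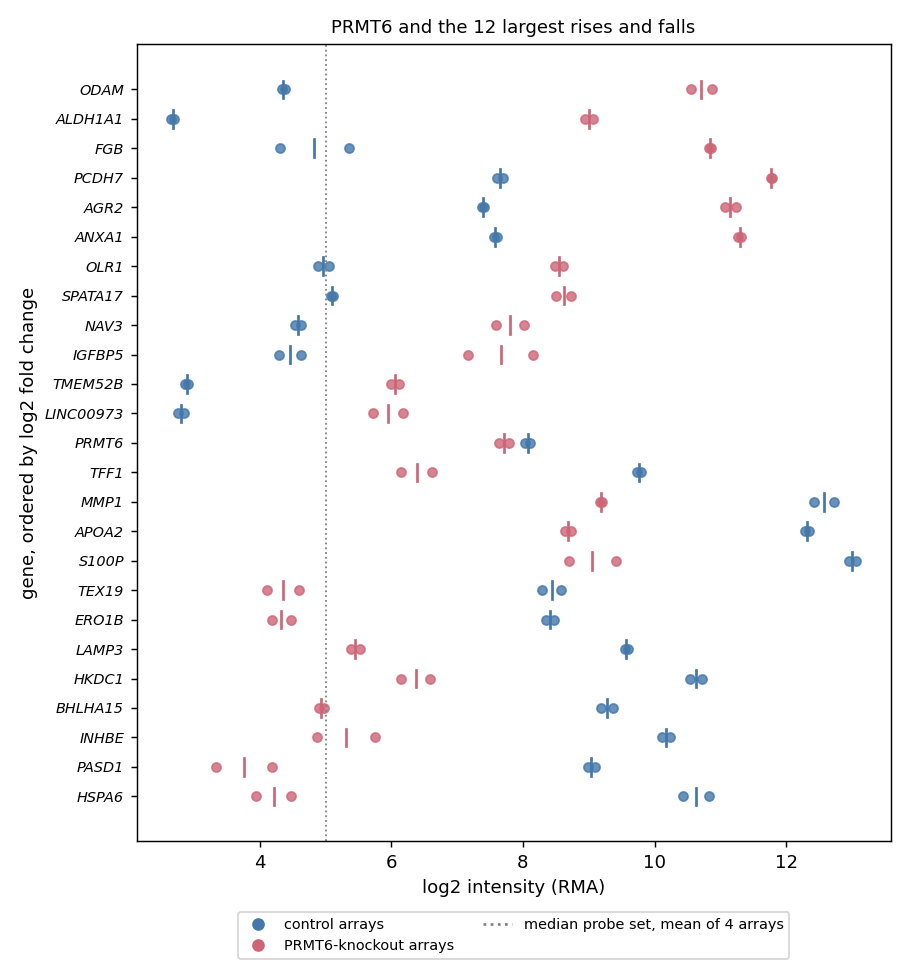
Log2 intensity (RMA, horizontal axis) of PRMT6 and of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array and a vertical tick at each group mean (n = 2 control, blue; n = 2 knockout, red); the dotted line marks the median probe set, averaged over the 4 arrays. The groups were far apart for HSPA6 (10.63 against 4.21) and ODAM (4.36 against 10.71) and close for PRMT6 (8.07 against 7.71).

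The 3 genes recalled from the published study of these cells were all higher in the knockout cells. PCDH7, a protocadherin, rose by 4.13 (SE 0.08), from 7.65 ± 0.06 to 11.77 ± 0.01 (SD, n = 2), or 17.5-fold (adjusted p = 0.00012, limma), and all 5 of its probe sets rose. IGFBP5, an insulin-like growth factor binding protein, rose by 3.20 (SE 0.33), or about 9.20-fold (adjusted p = 0.0032), with knockout arrays at 8.16 and 7.17 and a control mean of 4.46 that is not known to exceed background; 2 of its 6 probe sets rose. SCD, the stearoyl-CoA desaturase, rose by 0.53 (SE 0.08), or 1.45-fold (adjusted p = 0.010); all 4 of its probe sets rose, by 0.53 to 1.32. As a list they were called higher by camera (adjusted p = 0.0015; adjusted p = 0.45 with an estimated correlation), and 3 rose when adjusted over the list alone. The list was recalled from memory and not checked against a source, and a study of the same samples is not independent evidence of its direction. The SCD call was lost with any 1 array left out (adjusted p 0.050 to 0.10) and under reference gene scaling (0.066).

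The unfolded protein and ATF4 response restores folding in the endoplasmic reticulum and amino acid supply. DNAJB9, an endoplasmic reticulum co-chaperone, fell by 3.15 (SE 0.09), the stress transcription factor ATF3 fell by 2.81 (SE 0.12), DDIT3, which encodes CHOP, fell by 2.71 (SE 0.10), and SEL1L, a part of the degradation machinery of the endoplasmic reticulum, fell by 2.45 (SE 0.07). Of 31 measured members 29 fell, while VLDLR (0.26) and PHGDH (-0.01) did not pass the test. The list median was -1.50, and camera called the list lower (adjusted p = 8.3e-21; adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, 29 members fell and VLDLR rose. HSPA6, the gene with the largest fall, is a stress-inducible chaperone outside this list.

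Mitotic genes rose together. KIF20A, a kinesin of cytokinesis, rose by 1.66 (SE 0.08), the kinetochore motor CENPE rose by 1.22 (SE 0.08), the kinase AURKA rose by 1.18 (SE 0.08) and the proliferation marker MKI67 rose by 1.16 (SE 0.14). All 28 members of the G2/M and mitosis list rose, with 28 also adjusted over the list alone and a median of 0.88 (camera adjusted p = 5.6e-19; adjusted p = 0.45 with an estimated correlation). Among genes of DNA replication and the G1/S transition, UHRF1, which maintains DNA methylation, rose by 1.19 (SE 0.10), GINS2 by 1.14 (SE 0.12), MCM4 by 1.06 (SE 0.09) and MCM10 by 1.05 (SE 0.12). Of the 30 members 26 rose, the licensing factor CDC6 fell by 0.35, and PRIM1 (0.16), RFC4 (0.06) and E2F1 (-0.02) did not pass the test; adjusted over the list alone, 26 rose and 1 fell. The list median was 0.73 (camera adjusted p = 1.4e-12; adjusted p = 0.73 with an estimated correlation), and 0.43 under reference gene scaling. With single knockout arrays left out, the calls of MKI67, MCM10, GINS2, UHRF1 and, without knockout 2, MCM4 were lost. GINS2 was also lost with its gene-specific probe set (0.20, adjusted p = 0.29), which was dimmer (mean 5.57 against 7.83). MCM10 was 0.54 with its own.

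Genes of cholesterol biosynthesis rose as well. INSIG1, a sterol sensor partner and target of the sterol-responsive factor SREBP, rose by 3.01 (SE 0.09), or 8.05-fold. The reductase DHCR7 rose by 2.21 (SE 0.10), the thiolase ACAT2 by 2.18 (SE 0.08) and the squalene epoxidase SQLE by 1.58 (SE 0.08). Of 17 measured members 15 rose, with 15 also adjusted over the list alone, while STARD4 (-0.22) and HSD17B7 (0.14) did not pass the test. The list median was 1.21 (camera adjusted p = 1.5e-11; adjusted p = 0.45 with an estimated correlation). In the list of fatty acid synthesis and desaturation, FASN rose by 1.36 (SE 0.12), ACACA by 0.98 (SE 0.10) and ACLY by 0.85 (SE 0.08), whereas the desaturase-like FADS3 fell by 1.27 (SE 0.08). There 7 of 15 members rose and 2 fell (FADS3 and ELOVL7, -0.49), and the list was not called by camera (adjusted p = 0.070) but was called higher by fry (adjusted p = 0.046), and by camera without knockout 2 (adjusted p = 0.036), with the mean of probe sets (0.040) and under reference gene scaling (0.0050); its median of 0.22 became -0.08 under reference gene scaling. FASN, ACACA and ACLY lost their calls with either knockout array left out (highest adjusted p 0.059, 0.066 and 0.059).

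**Figure D2:**
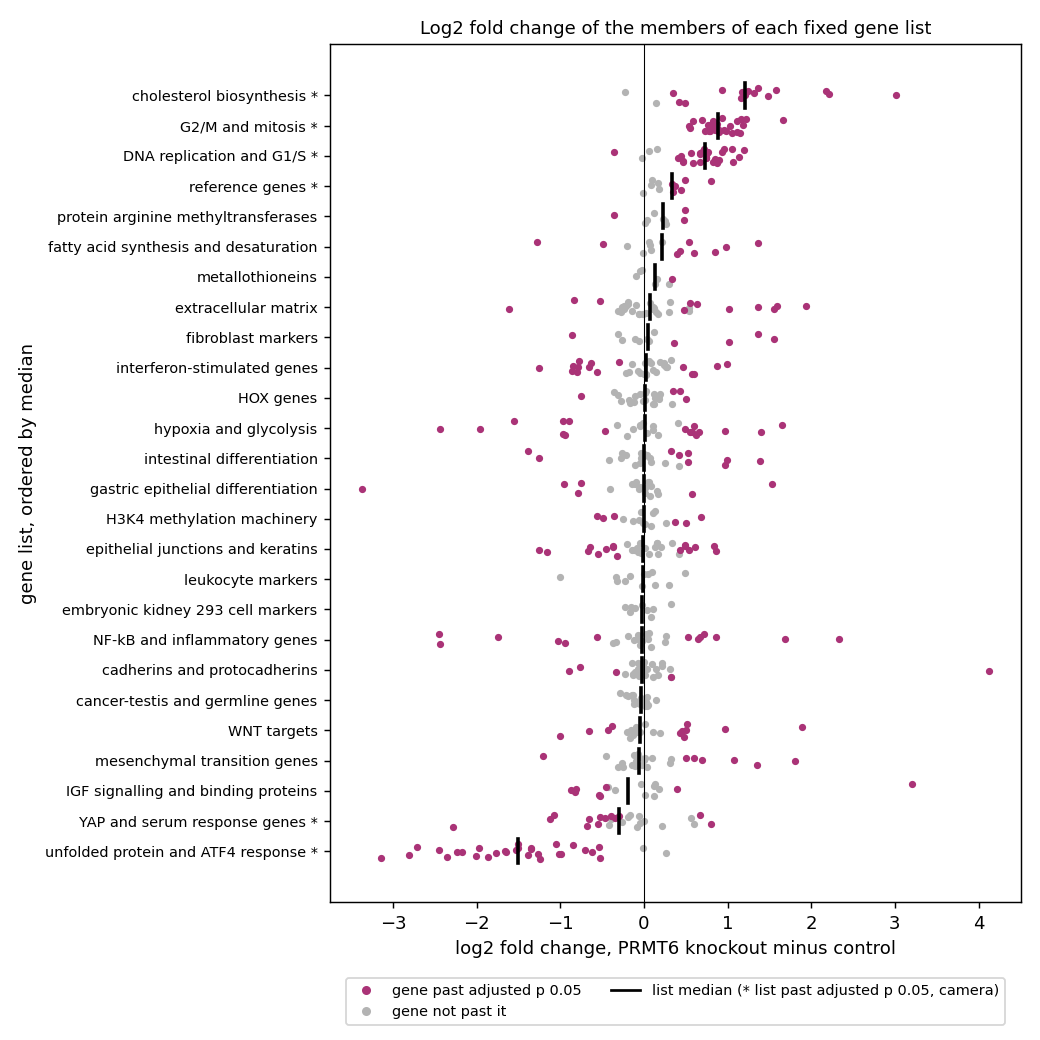
Log2 fold change (knockout minus control, horizontal axis) of every measured member of 26 of the 27 lists with at least 7 measured genes, 1 point per gene, with a black tick at each list median; purple points passed an adjusted p of 0.05 in limma, grey points did not, and asterisks mark lists called by camera. Cholesterol biosynthesis (median 1.21) and G2/M and mitosis (0.88) lay highest and the unfolded protein and ATF4 response lowest (-1.50); scaling to the reference genes, which lie among these lists, moved the medians of the first 2 to 0.91 and 0.58 and that of the last to -1.80.

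The YAP and serum response list was called lower (median -0.29, camera adjusted p = 0.0079; adjusted p = 0.73 with an estimated correlation), a call lost under reference gene scaling (adjusted p = 0.23) and not made by fry (adjusted p = 0.064). DUSP1, a phosphatase of stress-activated kinases, fell by 2.29 (SE 0.11), the Hippo kinase LATS2 fell by 1.13 (SE 0.09), and FOSL1, a subunit of AP-1, fell by 1.08 (SE 0.19). Of 25 members 11 fell, while MYL9 (0.81, SE 0.14) and the YAP target CCN2 (0.67) rose; adjusted over the list alone, 12 fell and 3 rose. The list joins YAP and serum response genes, LATS2 encodes a kinase that restrains YAP, and DUSP1 is an immediate early gene. Whether the falls reflect YAP activity was not tested. MYL9 rested on a probe set shared between transcripts. Its gene-specific probe set, dimmer with a mean of 5.62 against 8.53, gave -0.12 (adjusted p = 0.63). The MYL9 call was lost with either knockout array left out. FOSL1 lost its call without control 1 and with either knockout array left out (highest adjusted p 0.13).

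NF-kB and inflammatory genes went both ways. LCN2, a siderophore-binding lipocalin, fell by 2.44 (SE 0.08) and the chemokine CXCL8 fell by 2.43 (SE 0.12), while the chemokine CXCL2 rose by 2.33 (SE 0.07). IL1A changed by -1.75 (SE 0.16), a call not made by its gene-specific probe set (-0.02, adjusted p = 0.98). Both IL1A probe sets were dim, with means of 4.09 and 3.62. The gene-specific probe set of CXCL2 gave a smaller rise of 1.25. In all, 7 of 27 members rose and 6 fell, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.95). Among interferon-stimulated genes, RSAD2 fell by 1.25 (SE 0.08) and ISG20 fell by 0.86 (SE 0.12), whereas SAMD9 rose by 0.99 (SE 0.14) and PARP9 rose by 0.87 (SE 0.08). Of 34 members 5 rose (SAMD9, PARP9, IFIT3, IFIT1 and MX2) and 10 fell, or 8 and 10 adjusted over the list alone (camera adjusted p = 0.93). With single arrays left out, the calls of ISG20, SAMD9 and PARP9 were lost (highest adjusted p 0.099, 0.086 and 0.059), and PARP9 was also lost with its gene-specific probe set (0.36, adjusted p = 0.10).

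The epithelial regulators OVOL1 and ESRP1 fell by 1.26 (SE 0.08) and 1.15 (SE 0.08), while the desmosomal cadherin DSC2 rose by 0.86 (SE 0.08) and CD24 by 0.84 (SE 0.08). Among 32 epithelial junction and keratin genes 7 rose and 9 fell, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.95). Of 27 mesenchymal transition genes 6 rose, including S100A4 (1.81, SE 0.14), TGFBI (1.36, SE 0.13) and THBS1 (1.08, SE 0.12), and 1 fell, the repressor SNAI1 (-1.20, SE 0.20); adjusted over the list alone, 6 rose and 2 fell (camera adjusted p = 0.89; called higher by fry, adjusted p = 0.036). Of 35 extracellular matrix genes 8 rose, including COL4A6 (1.94, SE 0.18), NID1 (1.59, SE 0.22) and COL1A1 (1.56, SE 0.08), and 3 fell, LAMB3 (-1.61, SE 0.09), ECM1 (-0.84) and LAMB1 (-0.53) (camera adjusted p = 0.56; called higher by fry, adjusted p = 0.025). Of 12 fibroblast markers 4 rose, COL1A1, LUM (1.37, SE 0.11), COL3A1 (1.02, SE 0.21) and FAP (0.36), and PDGFRA fell by 0.86 (SE 0.12) (camera adjusted p = 0.56). In knockout cells LUM stood at 3.75 and COL3A1 at 3.80, below the median gene's level of 5.97, and neither rise was called with gene-specific probe sets (adjusted p = 0.66 and 0.53). THBS1 was 0.64 with its gene-specific probe set, and PDGFRA was lost with the mean of its probe sets (adjusted p = 0.24). Leaving out single arrays ended the calls of DSC2, CD24, THBS1, TGFBI, SNAI1, COL4A6, NID1, LUM, COL3A1 and PDGFRA (highest adjusted p 0.052 for TGFBI to 0.13 for COL3A1).

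Besides PCDH7, CDH17 (0.32) rose among 29 cadherins and protocadherins, while PCDH1 fell by 0.89 (SE 0.08), CELSR1 by 0.77 (SE 0.10) and CELSR3 by 0.33 (SE 0.09); adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.95; called higher by fry, adjusted p = 0.046). Of 16 genes of IGF signalling and binding, IGFBP5 (3.20) and IGFBP4 (0.40) rose and 6 fell, including IGFBP2 (-0.88, SE 0.12), IGFBP1 (-0.82, SE 0.14) and the insulin receptor INSR (-0.81, SE 0.11) (camera adjusted p = 0.42; called lower by fry, adjusted p = 0.035). The calls of PCDH1, CELSR1, CELSR3, IGFBP2, IGFBP1 and INSR were lost with single arrays left out (highest adjusted p 0.056 for PCDH1 to 0.23 for CELSR3). CELSR3 kept its probe set and value in the fit of gene-specific probe sets but lost its call there (adjusted p = 0.056). IGFBP1 was also lost with the mean of its probe sets (adjusted p = 0.066).

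Differentiation genes of the stomach and intestine changed singly. TFF1, a peptide of gastric surface cells, was 10.4-fold lower; the protease CTSE fell by 0.96 (SE 0.08), pepsinogen PGC fell by 0.79 (SE 0.08) and REG1A fell by 0.75. ANXA10 rose by 1.53 (SE 0.17) and SOX2 by 0.58, so that of 21 gastric genes 2 rose and 4 fell (camera adjusted p = 0.56). Of 25 intestinal genes 7 rose, including REG4 (1.39, SE 0.14) and the intestinal transcription factor CDX2 (1.00, SE 0.10), and 2 fell, LGALS4 (-1.39, SE 0.09) and CEACAM5 (-1.25, SE 0.08) (camera adjusted p = 0.56). Among 21 WNT targets DKK1, a secreted WNT antagonist, rose by 1.89 (SE 0.13) and AXIN2 by 0.98 (SE 0.08), with 7 rises in all. DKK4 (5.22 in control and 4.22 in knockout cells, SE of the difference 0.11), PROX1 (-0.66, SE 0.08), NKD1 (-0.43) and BAMBI (-0.38) fell (camera adjusted p = 0.89). The calls of CTSE, PGC, ANXA10, REG4, CDX2, AXIN2, DKK4 and PROX1 were lost with 1 or both of the knockout arrays left out in turn (highest adjusted p 0.053 for CTSE and AXIN2 to 0.077 for PROX1), and PROX1 was also lost with the mean of its probe sets (0.060).

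Hypoxia and glycolysis genes divided. DDIT4, an inhibitor of mTORC1, fell by 2.44 (SE 0.13), NDRG1 fell by 1.96 (SE 0.27) and the angiogenic factor VEGFA fell by 1.55 (SE 0.10), whereas the glycolytic aldolase ALDOC rose by 1.65 (SE 0.24). Of 28 members 9 rose and 8 fell (camera adjusted p = 0.95). NDRG1 and ALDOC lost their calls without either control array (highest adjusted p 0.068 and 0.073).

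Of 9 protein arginine methyltransferases PRMT7 rose by 0.49 (SE 0.11), PRMT2 rose by 0.48 (SE 0.09) and PRMT6 fell (camera adjusted p = 0.26); the list median of 0.23 became -0.07 under reference gene scaling. Among 16 genes of the H3K4 methylation machinery WDR5 (0.68, SE 0.10), KDM1A (0.51, SE 0.08) and DPY30 (0.37) rose, while KMT2C (-0.57, SE 0.09), KDM5B (-0.49, SE 0.10) and KMT2A (-0.35) fell (camera adjusted p = 0.95). KDM5B gave 0.36 (adjusted p = 0.080) with its gene-specific probe set. That probe set was dim, with a mean of 4.39 against 9.43 for the brightest. Gene-specific probe sets also ended the calls of PRMT2 (0.24, adjusted p = 0.12), HOXB6 (0.96, adjusted p = 0.11) and WDR5 (0.51). HOXD10 kept its probe set and value in that fit, with an adjusted p of 0.053. The mean of probe sets ended those of KDM5B, KMT2C and HOXD10 (adjusted p = 0.12, 0.12 and 0.54). Among genes that PRMT6 is reported to repress, THBS1 rose by 1.08 (SE 0.12), or 2.11-fold, and the cyclin-dependent kinase inhibitor CDKN1B fell by 0.44 (SE 0.08), while CDKN1A (-0.14) and CDKN2A (0.06) did not pass the test (camera adjusted p = 0.95, 4 genes measured). Of 24 HOX genes HOXB6 (0.50, SE 0.09), HOXB5 (0.44, SE 0.08) and HOXD10 (0.35, SE 0.09) rose and HOXB9 fell by 0.75 (SE 0.08), or 2 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.89). The calls given with an SE here, and that of PRMT6, were all lost with single arrays left out (highest adjusted p 0.069 for THBS1 to 0.24 for HOXD10). Those of PRMT7, PRMT2, KDM1A, HOXB6, HOXB5 and HOXD10 were also lost under reference gene scaling.

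Of 12 leukocyte markers 0 passed the adjusted test in limma and 4 had an unadjusted p below 0.05 (camera adjusted p = 0.95; fry adjusted p = 0.90). LYZ, which gastric epithelium also expresses, had a mean of 12.83 in control and 11.83 in knockout cells (SE of the difference 0.34, adjusted p = 0.096), with knockout arrays at 12.36 and 11.30. It was called lower under 4 alternatives, and its difference ran from -0.47 without knockout 2 to -1.53 without knockout 1. PTPRC had 0.49 (SE 0.16, adjusted p = 0.085) and was called higher with its gene-specific probe set (0.62, adjusted p = 0.020). That probe set read 2.36 and 2.16 in control and 2.77 and 2.99 in knockout arrays, far below the median gene's 5.97. These levels are not known to exceed background. Of 9 embryonic kidney cell markers, included because the lentivirus was made in such cells, 0 passed and 1 had an unadjusted p below 0.05 (camera adjusted p = 0.95; fry adjusted p = 0.94), with NEFL at 0.32 (SE 0.12) and WT1 at -0.22 (SE 0.11). Of 20 cancer-testis and germline genes 0 passed and 1 had an unadjusted p below 0.05 (camera adjusted p = 0.65, called lower by fry, adjusted p = 0.047). DDX4 had -0.28 (SE 0.12) and MAGEA12 -0.21 (SE 0.07). Both stood at 2.49 in knockout cells and are not known to exceed background. PASD1 and TEX19, which were among the largest falls, are a cancer-testis antigen and a germ-cell gene outside this list. Of 7 metallothioneins MT1X rose by 0.34 (SE 0.08), and its call was lost under 9 of 14 alternatives. These included any 1 array left out (0.28 to 0.40) and reference gene scaling (0.04, adjusted p = 0.72). The fit of gene-specific probe sets was another (adjusted p = 0.052). MT1X has no such probe set and kept its value there. Adjusted over the list alone 0 rose in limma, against 2 at an unadjusted p below 0.05 (camera adjusted p = 0.56; fry adjusted p = 0.19), and the list median of 0.13 became -0.17 under reference gene scaling.

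Among reference genes TFRC, the transferrin receptor, rose by 0.80 (SE 0.08), the glycolytic PGK1 by 0.49 (SE 0.10), HPRT1 by 0.44 (SE 0.08) and PPIA by 0.37 (SE 0.08). Of 11 measured members 6 rose, with 6 also adjusted over the list alone, while GUSB (0.18), ACTB (0.17), YWHAZ (0.10), B2M (0.08) and TBP (-0.01) did not pass the test. The median was 0.33, and 0.03 after scaling to these genes (camera adjusted p = 0.0033; adjusted p = 0.45 with an estimated correlation). It lay within the central 95% (-0.23 to 0.38) of the medians of 10000 random lists matched for abundance. Single arrays left out ended the calls of TFRC, PGK1, HPRT1 and PPIA (highest adjusted p 0.060, 0.13, 0.11 and 0.16), and scaling to the reference genes those of PGK1, HPRT1 and PPIA. PPIA was also lost with its gene-specific probe set (0.21, adjusted p = 0.42), and PPIA and HPRT1 with the mean of probe sets (adjusted p = 0.087 and 0.17).

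Across the 29 lists camera called 5 higher and 2 lower, and all 7 calls were also made with each array left out in turn. With an estimated correlation 0 lists were called, and 3 had an unadjusted p below 0.05. For cholesterol biosynthesis the estimated correlation was -0.004, below the preset 0.01, yet camera's unadjusted p went from 2.0e-12 to 0.017. Few degrees of freedom alone thus raise these p-values, so this alternative cannot tell whether correlation between genes undoes the calls. Fry called 12 lists, 9 higher and 3 lower, and 6 of these had no camera call: fatty acid synthesis, mesenchymal, extracellular matrix and cadherin genes higher, and IGF and cancer-testis genes lower. Reference gene scaling turned the medians of the HOX, interferon, extracellular matrix, gastric, intestinal, hypoxia and fibroblast lists, at most 0.08, to values from -0.30 to -0.22. That scaling lowers every gene by the same amount, so these turns are not particular to these lists. Counts adjusted over the list alone equalled those over all genes in the described lists where they are not given; 1 list, which camera did not call, is not described. In 9 lists, all without a camera call, the median, the mean and the direction of camera or fry differed in sign. These were the mesenchymal, NF-kB, interferon, gastric, WNT, hypoxia, cadherin, H3K4 and PRMT6-repressed lists.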

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

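All alternatives here were set down before the values were examined, except the reference gene scaling and the fit of every probe set, which were chosen after the data were seen. PRMT6 was lower under every alternative that refitted it and past the test in 7 of 14. It has 1 probe set, so alternatives that only chose probe sets or genes, or changed the prior or block, returned the same -0.3612. Their agreement in direction was fixed beforehand. The adjusted p was 0.052 in the fit of gene-specific probe sets. The change was -0.3643 after quantile normalization (adjusted p = 0.053) and between -0.4386 and -0.2838 with single arrays left out. Scaling to the reference genes gave 1112 genes higher and 9647 lower, 138 and 923 of them by 2-fold or more, and left 1 list lower, the unfolded protein and ATF4 response. The median of the reference genes (0.33) lay within the central 95% of abundance-matched random lists (-0.23 to 0.38), and which scaling is closer to the RNA content of the cells was not tested. With single arrays left out, 154 to 1371 genes rose and 354 to 1258 fell, and 150 to 292 rose by 2-fold or more. A lone array was there assumed to vary like the other group. The estimated correlation, with only the residual degrees of freedom, called 0 lists higher and 0 lower, and fry called 9 higher. Fitting every probe set on its own gave 3897 rises and 3653 falls, 536 and 791 of them by 2-fold or more, a count that repeats genes with several probe sets. With gene-specific probe sets KDM5B became 0.3552 (adjusted p = 0.080) and MYL9 -0.1179 (0.63). These probe sets were dimmer, with means of 4.39 and 5.62 against 9.43 and 8.53 for the brightest. They therefore do not show that the brighter probe sets were wrong, and the cause was not tested. No detection calls were used here, so signal near background could not be separated from absence.

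The labels give both groups the replicate numbers 1 and 2. With the number as a replicate block, PRMT6 was lower by -0.3612 (adjusted p = 0.076), 2035 genes rose and 1937 fell. Deviations from the group mean in arrays sharing a number had a correlation of 0.052 across genes. This low value gave little sign of pairing but cannot exclude that such arrays were handled together.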

Other observations

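The lists in this part were chosen after the changes above had been seen, so their p-values describe what was already noticed. WARS1 and SARS1, tRNA synthetases driven by ATF4, fell by 2.13 and 1.30; 10 of 11 such synthetases fell (median -0.91, camera adjusted p = 1.6e-08; adjusted p = 0.27 with an estimated correlation). Of 25 genes of translocation into and export from the endoplasmic reticulum 17 fell, including SEC24D (-2.01) and SEC63 (-1.16), and SPCS1 rose (camera adjusted p = 1.0e-08; adjusted p = 0.21 with an estimated correlation). Of 24 autophagy and lysosome genes 8 fell, including WIPI1 (-2.77), MAP1LC3B (-1.45) and SQSTM1 (-1.34), and MCOLN1 and ATP6V1A rose (camera adjusted p = 0.0064; adjusted p = 0.22 with an estimated correlation). Of 14 NRF2 targets and aldo-keto reductases 11 fell, including SRXN1 (-2.44), HMOX1 (-2.31) and TXNRD1 (-1.60), while AKR1C3 rose by 3.09 (camera adjusted p = 4.1e-07; adjusted p = 0.27 with an estimated correlation). Adjusted over the list alone, 11 synthetases, 18 genes of translocation and export, 9 of autophagy and 11 NRF2 targets fell. AKR1C3 has near-identical paralogs, and whether its probe set also reads those was not tested.

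Histone, proteasome and respiratory genes rose. H2BC4 rose by 2.43 and H1-4 by 1.38, with 10 of 12 replication-dependent histones higher (median 0.98, camera adjusted p = 4.1e-07, or 0.21 with an estimated correlation). Labelling was primed at the 3′ end of transcripts, and how well it reads histone transcripts without a poly(A) tail was not tested. PSMB3 rose by 0.75 among 17 of 23 proteasome subunits that rose (camera adjusted p = 1.1e-09; adjusted p = 0.27 with an estimated correlation), and their median of 0.52 became 0.22 under reference gene scaling. NDUFA2 rose by 0.99 among 16 of 22 oxidative phosphorylation genes that rose (camera adjusted p = 1.0e-08; adjusted p = 0.21 with an estimated correlation), with a median of 0.40 that became 0.10. Adjusted over the list alone, 10 histones, 21 proteasome subunits and 19 oxidative phosphorylation genes rose. Of 22 ribosomal protein genes 0 passed the test in limma, 0 had an unadjusted p below 0.05 and the median was -0.02, or -0.32 under reference gene scaling (camera adjusted p = 0.80). These genes were also chosen after the changes had been seen.

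The following tests were chosen after the results were seen; the predictions for the probe set, heat shock, synthetase and copy number tests were written before their values were computed, and those for the scaling and the cell cycle tests after. The unfolded protein and ATF4 list kept a median of -1.508 or lower under 4 other scalings. The arrays were already normalized and reference gene scaling lowered every gene alike, so this outcome was nearly fixed beforehand. It does not decide whether scaling was the source. Of the list's genes with a further probe set, 94.44% (17 of 18) were lower by that probe set too, which argues against single probe sets as the source. A list of mainly cytosolic heat shock genes, which also held the mitochondrial chaperones HSPE1 and HSPD1, had a median of 0.04751. HSPB1, HSPE1, HSPA4L, FKBP4 and CHORDC1 were higher and DNAJB4, BAG3, DNAJB1 and HSPH1 lower. The median lay above the bound written beforehand as speaking against a folding stress of the control cultures. That verdict was set aside after the values were seen. A median near 0 over members called both ways does not separate such a stress from none. HSPA6 and ZFAND2A had also been left out as already seen. ATF4-driven synthetases lay -1.258 from the other cytosolic synthetases (exact permutation p = 0.0017 across 11 and 6 genes, which are not independent replicates), as an ATF4 response predicts. The other synthetases had a median of 0.35, or 0.05 under reference gene scaling, with FARSB, KARS1 and RARS1 higher, and camera called them higher (adjusted p = 0.0047; adjusted p = 0.36 with an estimated correlation), so part of the difference is their rise. These tests did not separate loss of PRMT6 from stressed control cultures or a difference between clones, and the source of the lower list was left open.

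The medians of the cell cycle lists lay at least 0.3127 above the highest of 10000 random lists matched for abundance, and the smaller median under 4 other scalings was 0.4304. The comparison with random lists argues against a shift shared by genes of like abundance as the source. The other scalings do not decide the question, because the arrays were already normalized and reference gene scaling lowered every gene alike. Growth rate, culture density and passage were not measured here, so the cause of the rise was left open.

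Of 384 windows of 25 neighbouring genes, 0.5208% (2 windows) lay outside the range of shuffled windows, both lower, from MPPE1 to OSBPL1A (-0.40) and from BTN2A1 to HLA-J (-0.33). This argues against copy number as the source of most changes. Chromosome 18, which holds the window from MPPE1 to OSBPL1A, had a median of -0.10 over its brighter genes, with 23 higher and 45 lower. Smaller copy number differences, off-target edits and clonal selection were not tested, and any difference between the cultures unrelated to PRMT6 is confounded with the knockout in these arrays.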
